A study of Ovis aries with 9 samples.

How the data were processed

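Liver RNA was sequenced from Tan sheep, a fat-tailed Chinese breed, given a basal diet (control) or the same diet with 1% or 2% succinate, the dicarboxylic acid that succinate dehydrogenase oxidises in the tricarboxylic acid cycle. Per the labels, 30 male sheep aged 5 months were kept in 5 stalls per group with 2 sheep per stall, and a pretrial period of 10 days preceded a trial of 60 days. The deposited series holds 9 libraries, 3 per group. Per the labels' protocols, liver was collected directly at slaughter and kept in liquid nitrogen, total RNA was extracted with TRIzol, libraries were made with the NEBNext Ultra RNA kit, and paired-end reads were generated on an Illumina platform. The labels do not say that each library came from a separate animal or stall, so p-values measure only the spread between these libraries, which may in part be technical.

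Groups were taken from the treatment label. That label places 3 libraries at 1%, but the title of 1 of them (library 3 at 1%) gives 2% in brackets. It was kept at 1%, and every comparison was repeated with it at 2%. The title of the series concerns muscle fibres and meat quality, while the tissue label of every library is liver, so the levels of liver and muscle markers were examined first. The design text numbers the dosed groups differently from the library titles, and doses are therefore used here in place of group codes.

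The values are FPKM per gene (fragments per kilobase of gene model, scaled to the reads of each library) as deposited by the authors, per the file headers, in 1 table of 21257 genes. The aligner, counter and annotation are not given in the sources used here. The submitters' processing notes list the mouse builds GRCm38 and mm10, whereas the gene names are those of the sheep RefSeq annotation. Of the 21257 names, 20169 matched the sheep reference table (assembly ARS-UI_Ramb_v3.0), which was used for names only, and 5117 genes carried only a LOC identifier. The build behind the values is not settled, and no coordinates are given. A total of 13 mitochondrial locus tags were replaced by their gene symbols. Strand use in counting and the treatment of reads shared between paralogs are not given, so genes with near-identical copies are uncertain.

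Depth was read from the values. Among the 17402 genes above 0 in at least 2 libraries, the FPKM values of 17400 (99.99%) were whole multiples of the worth of 1 read, within a tolerance of 0.01, and 728 genes above 0 in 1 library were left out of this step. The recovered reads numbered 12233659 to 16344446 per library, with a median of 13719556. These reads served for a check with voom, for the simulated data, for relative gene length and for the comparison of pairs of libraries. All other tests used FPKM, the deposited unit. The smallest chi-square per degree of freedom between any pair of libraries was 34.3, so no library was a copy of another.

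Tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), on genes with an FPKM of at least 1 in at least 3 of the 9 libraries, which left 11944 genes. A log2 change on this scale understates the change of genes with low FPKM. All 9 libraries entered 1 fit, with empirical Bayes moderation and an intensity trend, and each comparison was a contrast of group means. The trend with dose was a separate fit on succinate percent as a number. P-values are two-sided and were adjusted by the Benjamini-Hochberg method across the tested genes, with a threshold of 0.05. Gene lists (48 in all, covering energy and succinate metabolism, liver functions, stress and immune programs, muscle fibre types and markers of other cell types) were written before the data were examined, as were the comparisons of the report with their tests, and most of the alternatives listed below. The comparison of either dose with control and the tests that belong to it were added later. The 39 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Preset-correlation camera compares a list with all other genes, and its calls are given beside the p obtained with an estimated correlation. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 handled the table and the plots.

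The named genes followed a rule fixed before the data were examined. For each comparison these were the 8 passing genes per direction with the largest change that have a symbol. Where fewer than 5 genes passed, the 5 genes per direction with the smallest p, a symbol and groups that did not overlap were named as not passing. To these were added the 3 members with the smallest p of each called list, the 2 with the smallest p of the lists for the tricarboxylic acid cycle, succinate handling, fatty acid synthesis, fatty acid oxidation and gluconeogenesis, and in every case SUCNR1, SDHA, SDHB, SLC25A10, ALB, APOA1, ACTA1 and MYH7. MYH7 was not analysed here. Some genes selected by this rule are not given here. Genes named outside the rule are said to be so.

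The procedure was tested on simulated data built on the 1% against control comparison, with 11816 genes in that step. At a true change of 4-fold, 52 of 66 changed genes (78.8%) were recovered. At 2-fold 20 of 67 (29.9%) and at 1.5-fold 4 of 67 (5.97%) were recovered, with 2 false calls among unchanged genes. A shifted list was called, and 0 of the 39 unchanged lists were. Simulated genes were drawn independently and these lists held random genes. The list result therefore does not cover lists whose members vary together between libraries. Alternatives changed the pseudocount (0.1), the filter (none, or a mean FPKM of at least 5), the scaling between libraries (quantile or median ratio), the variance model, the weights, the set of groups fitted, a block on replicate number, the dose of the library with conflicting labels, and the threshold (unadjusted p under 0.05 with at least a 1.5-fold change), or left out each library in turn.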

Results

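Gene expression was measured in the liver of sheep fed a control diet or a diet with 1% or 2% succinate, with 3 libraries per group. Recovered reads ranged from 12233659 to 16344446 per library, and 15911 to 16441 genes were above 0 in each. The tissue was examined first because the series concerns muscle while the labels name liver. Hepatocyte markers (plasma proteins such as albumin, apolipoproteins and fibrinogen) had a median FPKM of 2157 to 3740 in the 9 libraries, and skeletal muscle markers (such as actins, myosins and creatine kinase of muscle) a median of 0 to 0.0114. The albumin gene ALB stood at 25150 ± 16000 FPKM in controls, 24610 ± 12400 at 1% and 37440 ± 7740 at 2% (SD, n = 3), and APOA1 at 332.9 ± 70.7, 245.2 ± 61.6 and 349.2 ± 37.6. The muscle actin gene ACTA1 reached at most 0.217 FPKM in any library, and the highest value of any muscle marker was 11.1 FPKM. The mean log2 ratio of hepatocyte to muscle marker level, each a median FPKM with 1 added, was 11.44 ± 0.31 (SD over the 9 libraries). As the muscle medians were near 0, the added 1 stands in for the muscle level. The ratio is thus a lower bound that follows the hepatocyte level.

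The first comparison asked what 1% succinate changed in the liver. USP2, a ubiquitin-specific protease whose transcript follows the daily clock in rodent liver, fell by 1.65 on the log2 scale (SE 0.175, adjusted p = 0.022, limma), from 4.09 ± 0.644 FPKM in controls to 0.623 ± 0.272 (SD, n = 3 per group). SMIM10, a small integral membrane protein, fell by 1.61 (SE 0.172, adjusted p = 0.022), from 8.81 ± 1.07 to 2.24 ± 0.651. These were the only genes of 11944 to pass, 0 higher and 2 lower. At an unadjusted p under 0.05 there were 1778 genes, 252 higher and 1526 lower, against 597 expected by chance. The median log2 change of all tested genes was -0.139, and quantile or median-ratio scaling moved it to 0.01 or -0.011 and the split to 832 higher and 702 lower or to 873 higher and 771 lower. The split was 712 higher and 1143 lower without control 1, 96 and 754 without 1% library 3, and 69 and 497 with the library of conflicting labels placed at 2%, a total below that expected by chance. Of 10 divisions of these libraries into groups of 3, the highest other than the real one gave 1460 genes at this threshold. Changes at 1% are given as fitted, and for gene lists also relative to the median of all tested genes.

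Genes with the smallest p that did not pass included the clock activator ARNTL at 9.49 ± 2.87 FPKM against 3.02 ± 0.76 in controls (log2 change 1.37, adjusted p = 0.089) and the clock repressor CRY1 at 5.8 ± 1.75 against 2.1 ± 0.483 (adjusted p = 0.181). ANKS6, an ankyrin repeat protein of the primary cilium, stood at 4.18 ± 0.17 against 1.82 ± 0.198 (adjusted p = 0.089). GPHN, a scaffold and molybdenum cofactor enzyme, had a log2 change of 0.77 and the adaptor DOK5 1.30. On the lower side, the costimulatory receptor TNFRSF9 was at 0.956 ± 0.545 against 6.05 ± 1.21 FPKM (log2 change -1.88, adjusted p = 0.0858), LRRC19 had a log2 change of -1.25 and the kainate receptor subunit GRIK4 one of -1.21. Groups of 3 against 3 separate by chance in 10% of genes.

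The endoplasmic reticulum stress list was called higher at 1% (camera adjusted p = 7.21e-08), with 20 of 23 members above control and a median log2 change of 0.389, or 0.528 relative to the median of all genes. The adjusted p was 0.861 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Its leading members were XBP1, the transcription factor of the unfolded protein response, at 335.7 ± 88.3 against 157.1 ± 56.6 FPKM, the chaperone HYOU1 at 63.1 ± 43.6 against 22.8 ± 16.2, and the co-chaperone DNAJB9 at 134.7 ± 75.1 against 61.8 ± 28.4. The fibrinogen gene FGA, an acute phase product of hepatocytes, stood at 9905 ± 3951 FPKM against 5342 ± 1686 and did not pass (adjusted p = 0.336). It was named after its values were seen. The acute phase list was split, with 8 of 14 members above control and 6 below. It was not called (camera adjusted p = 0.0549, and 0.861 with an estimated correlation). Cholesterol synthesis was called higher (adjusted p = 0.0186, and 0.861 with an estimated correlation), with 13 of 21 members above control and a median of 0.071, or 0.21 relative to all genes. Log2 changes were 0.65 for STARD4, a sterol carrier, and 0.57 for HSD17B7, a sterol reductase. The heat shock list was called higher (adjusted p = 0.0268, and 0.861 with an estimated correlation, median 0.15, or 0.288 relative to all genes, mean 0.05), with the mitochondrial chaperonin HSPD1 at 134.7 ± 24.1 against 85.8 ± 1.17 FPKM and HSP90AA1 at a log2 change of 0.57, while DNAJB1 had one of -0.75. Antigen presentation was called lower (adjusted p = 0.0347, and 0.861 with an estimated correlation), with 9 of 9 members below control and a median of -0.485, or -0.346 relative to all genes. It included the immunoproteasome subunits PSMB9 (log2 change -0.94) and PSMB8 (-0.62) and the peptide transporter TAP2 (-0.64), and 1 member passed adjusted over the list alone. Without a library some of these calls were lost. Antigen presentation was not called without control 1 (adjusted p = 0.057), control 2 (0.232), 1% library 2 (0.103) or 2% library 2 (0.0631). Cholesterol synthesis was not called without control 1 (0.142), control 2 (0.251) or 1% library 1 (0.663), and its median turned to -0.036, -0.193 and -0.316. Heat shock was not called without control 2 (0.249), control 3 (0.106) or 1% library 3 (0.124). Endoplasmic reticulum stress was called without each library. The count of 4 lists became 8 without control 1 and 11 without 1% library 1. Cholesterol synthesis and heat shock were not called after quantile (0.111 for both) or median-ratio scaling (0.0887 and 0.068). With the library of conflicting labels placed at 2% heat shock was not called (median 0.044, adjusted p = 0.15), while the other 3 lists were. T and NK cell markers had a median log2 change of -0.578, or -0.44 relative to all genes, in the same comparison (adjusted p = 0.158).

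Of the 18 tested members of the circadian clock list, 3 were higher and 8 lower at 1% when adjusted over the list alone, and 7 did not pass. Over all genes 0 passed. Camera, which tests for 1 direction, did not call the list (adjusted p = 0.252, and 0.861 with an estimated correlation) but called it lower after quantile scaling (0.0459), and fry's test for change in either direction gave an adjusted p of 0.000429. The latter test also called mitochondrial biogenesis and protein degradation (0.0325 each). DBP, an output transcription factor of the clock, stood at 8.95 ± 3.03 against 31.4 ± 9.01 FPKM and PER3 at 2.75 ± 1.05 against 12.3 ± 4.18. Both were named after their values were seen.

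Genes of succinate and fuel metabolism did not pass at 1%. The succinate receptor gene SUCNR1 lay under the filter, at 1.11 ± 0.819 FPKM in controls, 0.62 ± 0.163 at 1% and 0.779 ± 0.171 at 2%. SLC13A3, a sodium-coupled dicarboxylate transporter that takes up succinate, was at 9.36 ± 2.4 against 4.71 ± 1.05 FPKM (log2 change 0.85, adjusted p = 0.249), and the mitochondrial dicarboxylate carrier SLC25A10 at 24.4 ± 7.52 against 44 ± 7.07 (-0.86, adjusted p = 0.261). Succinate dehydrogenase subunits did not pass, with log2 changes of -0.34 (SE 0.198) for SDHA and -0.12 (SE 0.179) for SDHB, the latter 0.024 after median-ratio scaling. In the tricarboxylic acid cycle 0 of 24 genes passed adjusted over the list alone, with citrate synthase CS at a log2 change of 0.50 and fumarase FH at -0.60. In fatty acid oxidation 3 of 25 genes, all lower, passed adjusted over the list alone, while the list was not called (camera adjusted p = 0.0844, median -0.391, or -0.252 relative to all genes). After quantile scaling it was called lower (0.0158), as were the lists for bile acids (0.009), xenobiotic metabolism (0.0293), antioxidant defence (0.0293) and lipid transport (0.0344). With an estimated correlation, before that scaling, the adjusted p of these 5 lists was 0.861 to 0.888. PDK4, the kinase that switches off pyruvate dehydrogenase, was at 22.2 ± 7.31 against 85.8 ± 11.6 FPKM and CPT1B at 2.92 ± 0.809 against 6.65 ± 1.21. In fatty acid synthesis, which was not called (adjusted p = 0.31), the lipogenic regulator SREBF1 had a log2 change of -0.59 and the desaturase SCD5 of -0.67. In gluconeogenesis (adjusted p = 0.303) the coactivator PPARGC1A was at -0.99 and the aminotransferase GOT1 at 0.99. The 35 lists that were not called had a camera adjusted p of at least 0.0549, that of the acute phase list.

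The 2 calls at 1% depended on the libraries. The count was 0 without any 1 of the 3 controls, without 1% library 2 or 3 and without 2% library 1 or 2, and it was 4 without 1% library 1. USP2 exceeded 1 FPKM only in controls, so it fell below the filter and was not tested when a control was left out, while SMIM10 then had an adjusted p of 0.141 to 0.163. It was 0 under each scaling, with the library of conflicting labels placed at 2%, and in the fit of these groups alone.

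**Figure D1:**
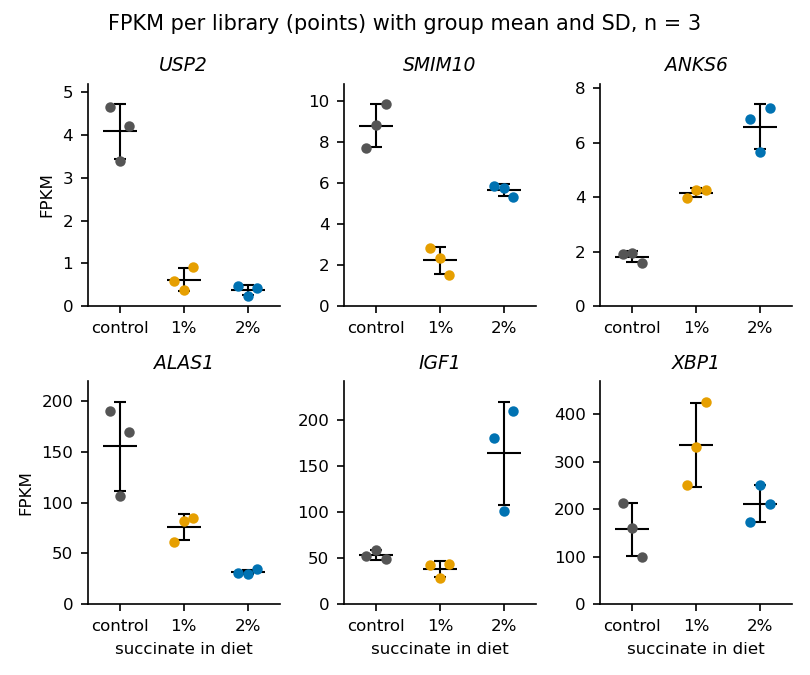
FPKM per library (points) for 6 named genes in the control, 1% and 2% succinate groups, with the group mean (bar) and SD (whiskers), n = 3. USP2 lay below control in all 6 succinate libraries, SMIM10 was lowest at 1%, ANKS6 and ALAS1 were ordered by dose, IGF1 was highest at 2%, and the mean of XBP1 was highest at 1%.

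A parallel comparison set 2% succinate against control. ALAS1, the rate-limiting enzyme of heme synthesis, fell by 2.22 on the log2 scale (SE 0.238, adjusted p = 0.0155, limma), from 155.6 ± 43.8 FPKM in controls to 31.6 ± 2.44 (SD, n = 3 per group). USP2 fell by 1.88 (SE 0.175, adjusted p = 0.00832) to 0.379 ± 0.126 FPKM, and CIART, a repressor of the clock, fell by 1.54 (SE 0.204, adjusted p = 0.0469) from 2.62 ± 0.575 to 0.237 ± 0.114. ARNTL, whose product drives the daily clock together with CLOCK, rose by 1.68 (SE 0.213, adjusted p = 0.0406) to 11.7 ± 1.03 FPKM. ANKS6 rose by 1.43 (SE 0.136, adjusted p = 0.00832) to 6.6 ± 0.84 FPKM. With 1 further gene known only by an identifier, 6 genes passed, 2 higher and 4 lower. At an unadjusted p under 0.05 there were 619 genes, 127 higher and 492 lower, against 597 expected by chance. Quantile scaling moved that split to 354 higher and 371 lower, and median-ratio scaling to 271 higher and 390 lower. It was 434 higher and 367 lower without control 1, 90 and 297 without 2% library 3, and 200 and 844 with the library of conflicting labels placed at 2%. Of 10 divisions of these libraries into groups of 3, the real one included, 4 gave as many genes at this threshold. The highest other gave 1119. The median log2 change of all tested genes was -0.055.

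The circadian clock list was again split: 4 members were higher and 9 lower when adjusted over the list alone, 2 of 18 passed over all genes and 5 did not pass either way. Camera did not call it (adjusted p = 0.0714, and 0.875 with an estimated correlation), and fry's test for change in either direction gave an adjusted p of 9.22e-05. The latter test also called myogenic regulation (0.00387), a list that holds IGF1. Beside ARNTL and CIART, DBP stood at 8.6 ± 0.669 against 31.4 ± 9.01 FPKM (log2 change -1.72, SE 0.265), NR1D2, a nuclear receptor that represses ARNTL, at 6.47 ± 1.92 against 18.8 ± 3.38 (-1.43, SE 0.22), and CRY1 at 7.27 ± 1.73 against 2.1 ± 0.483 (1.40, SE 0.23). PER2 was at 13.5 ± 3.21 against 14 ± 4.02 FPKM. The 4 genes other than ARNTL and CIART were named after their values were seen.

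**Figure D2:**
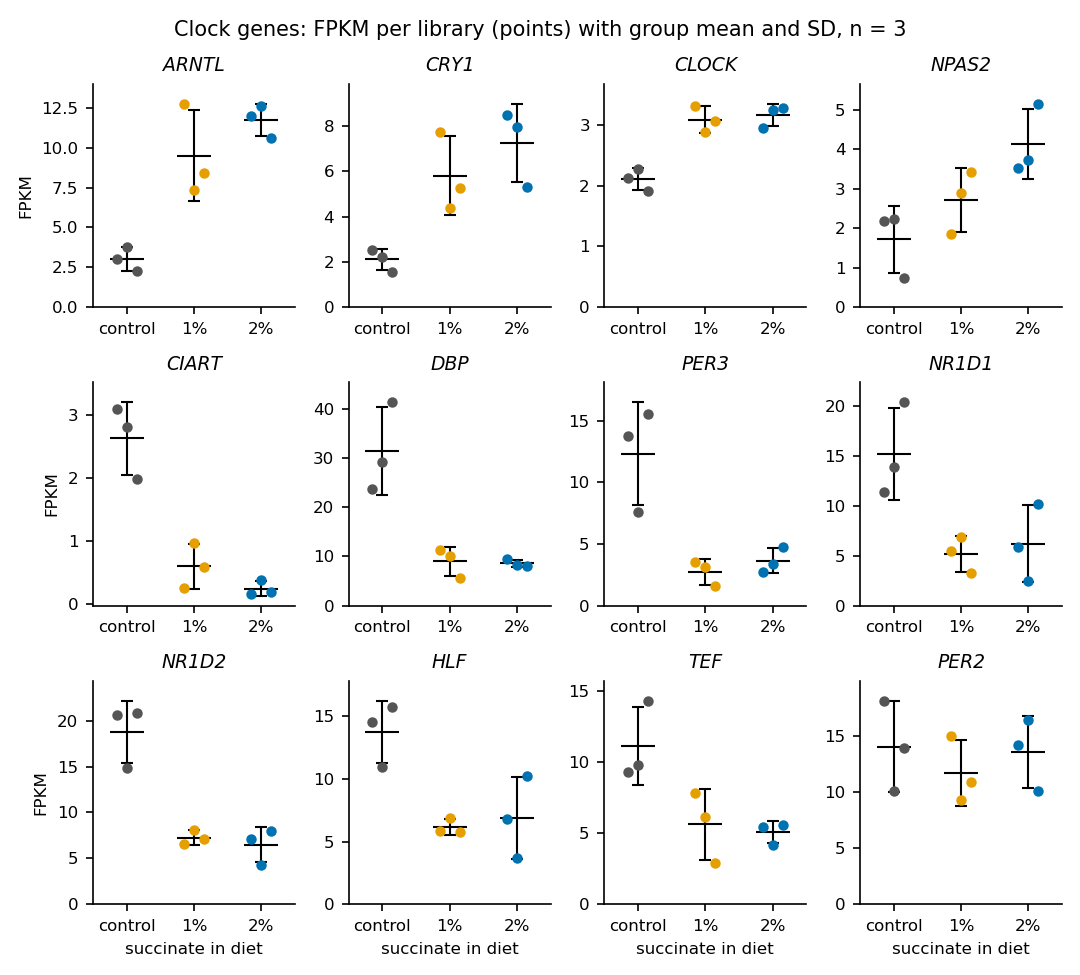
FPKM per library (points) for 12 genes of the circadian clock list in the control, 1% and 2% succinate groups, with the group mean (bar) and SD (whiskers), n = 3. In the 6 succinate libraries ARNTL, CRY1 and CLOCK lay above every control, and CIART, DBP, PER3, NR1D1, NR1D2, HLF and TEF lay below every control, while NPAS2 and PER2 overlapped.

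Markers of stellate cells and fibroblasts were called higher at 2% (camera adjusted p = 0.00232), with 6 of 6 members above control and a median log2 change of 0.664. The adjusted p was 0.875 with an estimated correlation, and 0 members passed adjusted over the list alone. The collagen genes COL1A1 (17.7 ± 14.3 against 6.23 ± 2.41 FPKM) and COL1A2 (20.9 ± 16.8 against 6.54 ± 0.693) were high in 2% libraries 1 and 3, at 16.8 and 32.3 FPKM for COL1A1, and not in 2% library 2, at 3.85 FPKM. DCN had a log2 change of 0.40. Nuclear-encoded oxidative phosphorylation was called lower (adjusted p = 0.0074, and 0.875 with an estimated correlation), with 48 of 54 members below control and a median of -0.196. NDUFV1 (-0.45), NDUFC2 (-0.55) and NDUFA11 (-0.49), all of respiratory complex I, led it. Ribosomal proteins were called lower (adjusted p = 0.0074, and 0.875 with an estimated correlation), with 51 of 62 members below control and a median of -0.145, which was -0.015 after quantile scaling. The leading members were RPS19 (-0.47), RPS21 (-0.57) and RPL6 (-0.69). Bile acid synthesis and transport was called lower (adjusted p = 0.0242, and 0.875 with an estimated correlation), with 11 of 11 members below control and a median of -0.386. It was led by the bile acid enzymes AKR1D1 (-0.66) and SLC27A5 (-0.73) and the nuclear receptor NR0B2 (-0.53). In these 3 lists 0 members passed adjusted over the list alone. Without 2% library 3 the fibroblast markers (adjusted p = 0.155), oxidative phosphorylation (0.453), ribosomal proteins (0.155) and the bile acid list (0.155) were not called. Without control 3 oxidative phosphorylation (0.706), ribosomal proteins (0.368) and the bile acid list (0.328) were not called, nor was the bile acid list without 2% library 2 (0.132). Quantile scaling ended the same 3 calls (0.0649, 0.345 and 0.0502). The count of 4 lists became 11 without control 1, 8 without control 2, 1% library 1 or 2% library 1, 9 without 1% library 3 and 1 without 2% library 3.

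Succinate and fuel genes did not pass at 2% either. SLC13A3 was at 3.4 ± 0.62 FPKM (log2 change -0.37, adjusted p = 0.95), SLC25A10 at 32.7 ± 5.11 (-0.42), SDHA at 128.7 ± 17.5 (-0.22) and SDHB at 11.6 ± 0.71 (0.02). SREBF1 stood at 7.77 ± 0.41 against 12.2 ± 0.916 FPKM (-0.59, adjusted p = 0.679) and the acyltransferase GPAM at 14.6 ± 1.2 against 28.7 ± 5.21 (-0.92). Other leading members were IDH2 (0.90) and CS (0.34) of the tricarboxylic acid cycle, SLC22A5 (-0.80) and ECI2 (-0.68) of fatty acid oxidation, and GPT2 (-0.78) and SLC37A4 (-0.52) of gluconeogenesis. The lists not called had a camera adjusted p of at least 0.0591.

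The count of 6 was 0 without control 1, 2% library 1 or 2% library 3, 1 without control 2, control 3 or 2% library 2, and 0 in the fit of these groups alone. USP2 and CIART fell below the filter when a control was left out. Without 1% library 3, which enters only the estimate of spread, ARNTL (adjusted p = 0.0759) and CIART (0.0936) did not pass. The count was 1 with the library of conflicting labels placed at 2%, 1 with the filter at a mean FPKM of 5, 3 without a filter and 3 with voom on recovered reads.

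A further comparison set the doses against each other. With limma, 0 of 11944 genes passed, and the smallest adjusted p was 0.417. Voom on recovered reads also gave 0. At an unadjusted p under 0.05 there were 894 genes, 740 higher and 154 lower at 2%, against 597 expected by chance. The split was 456 higher and 399 lower after quantile scaling and 495 higher and 447 lower after median-ratio scaling. It was 140 higher and 117 lower, fewer than expected by chance, with the library of conflicting labels placed at 2%. Without a library it was 1158 and 221 (1% library 1), 389 and 125 (1% library 3), 389 and 92 (2% library 1) or 447 and 91 (2% library 3). Of 10 divisions of these libraries into groups of 3, the real one included, 2 gave as many genes at this threshold. The highest other gave 1172. IGF1, the liver-made growth factor, had the smallest p, at 163.7 ± 56.1 FPKM at 2%, 38 ± 8.4 at 1% and 53.1 ± 5.38 in controls (log2 change 2.04, SE 0.282). Other genes with higher values at 2% were the phosphatase PTPN18 (1.34), SMIM10 (1.06), the creatine synthesis enzyme GATM at 1016 ± 212 against 374.1 ± 67 FPKM (1.43) and SH3RF2 (1.12), each with an adjusted p of 0.423. Values were lower at 2% for SLC13A3 (-1.22), the sphingosine phosphate lyase SGPL1 (-0.97), ALAS1 (-1.23), the glycerol kinase GK (-0.98) and the receptor kinase ROS1 (-1.41), also at 0.423. Without 1% library 1, 1 gene passed.

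By camera 8 lists were called in this comparison, 2 higher and 6 lower at 2%, and each had an adjusted p of 0.889 with an estimated correlation. The median log2 change of all tested genes was 0.071. After quantile scaling 5 lists were called higher and 3 lower, 5 of them among these 8, and heat shock (0.0546), the urea cycle list (0.271) and the glucocorticoid response (0.114) were not called. After median-ratio scaling the urea cycle list (0.107) and the glucocorticoid response (0.0688) were not called. Endoplasmic reticulum stress was lower at 2% than at 1% (adjusted p = 5.8e-05), with 20 of 23 members lower and a median log2 change of -0.355, led by SDF2L1 (-0.93), XBP1 (-0.65) and ATF6 (-0.39). Placing the library of conflicting labels at 2% turned the median to 0.117 (adjusted p = 0.572). That placement kept 3 of the 8 calls (cholesterol synthesis, urea cycle and ribosomal proteins) and also ended those of heat shock (median 0.01, adjusted p = 0.743), glucocorticoid response (0.15, 0.783), extracellular matrix (0.144, 0.22) and fibroblast markers (0.433, 0.154). Heat shock (adjusted p = 0.00579, 11 of 13 lower) was led by HSPD1 (-0.29), HSPB8 (-0.33) and HSPB1 (-0.35), and cholesterol synthesis (0.00218, 16 of 21 lower) included FDPS (-0.84) and PMVK (-0.61). Ribosomal proteins (0.00119, 42 of 62 lower) included RPS19 (-0.33) and FAU (-0.43). In the glucocorticoid response (0.0303, 9 of 14 lower) the aminotransferase TAT, a gene induced by glucocorticoids, stood at 69.4 ± 19.4 against 144.7 ± 31 FPKM, and 1 member passed adjusted over the list alone. ZBTB16 was at -0.56 and the receptor NR3C1 at 0.22. The urea cycle and amino acid list was called lower (0.0484), but 15 of 27 members were lower. Its median was -0.016, or -0.087 relative to all genes, with a mean of -0.106. Its leading members, TAT (-1.07), AASS (-0.54) and AMT (0.88), degrade tyrosine, lysine and glycine. Extracellular matrix was higher at 2% (0.02, 24 of 26 members, median 0.325), led by MMP2 (1.00) and FBN1 (0.53), whereas CCN2 was at -1.04. Fibroblast markers were higher too (0.039, 6 of 6, median 0.667), led by COL3A1 (0.97), COL1A1 (1.15) and PDGFRB (0.33). Leaving out 1 library ended every one of these calls for at least 1 choice. Without 1% library 3 the adjusted p was 0.0919 for endoplasmic reticulum stress and 0.0957 for heat shock. Their medians were then -0.104 each, against -0.355 and -0.201 with all libraries. Without 1% library 1 the adjusted p was 0.497 for cholesterol synthesis and 0.0856 for ribosomal proteins, with medians that turned to 0.128 and 0.014. The glucocorticoid response was not called without 1% library 1 (0.0506), 1% library 3 (0.201), 2% library 2 (0.051) or 2% library 3 (0.171). Its median was -0.007 without 1% library 3, against -0.228 with all libraries. The urea cycle list was not called without control 1 (0.0641), 1% library 1 (0.639), 1% library 2 (0.0593), 2% library 2 (0.0671) or 2% library 3 (0.192), and its median turned to 0.036 without 1% library 1, 0.05 without 2% library 2 and 0.041 without 2% library 3. Extracellular matrix was not called without 1% library 1 (0.091), 1% library 3 (0.0808), 2% library 1 (0.255) or 2% library 3 (0.402). Fibroblast markers were not called without control 1 (0.0803), 1% library 1 (0.091), 1% library 2 (0.0593), 1% library 3 (0.0808), 2% library 1 (0.123) or 2% library 3 (0.479). The count of 8 lists became 4 without 1% library 3 and 5 without 2% library 3.

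Among fuel genes, PDK4 was at 74.1 ± 35.6 FPKM at 2% against 22.2 ± 7.31 at 1% (log2 change 1.63, adjusted p = 0.423), with CPT1B at 0.66. The glucose-6-phosphatase gene G6PC1 was at 73.8 ± 18 against 38.1 ± 10.8 (0.94, adjusted p = 0.511) and pyruvate carboxylase PC at 0.81. SDHAF1 (-0.51), SCD5 (0.54), ME1 (0.69), SDHA (0.12), SDHB (0.14) and SLC25A10 (0.45) did not pass. SLC25A10 was at -0.08 with the library of conflicting labels at 2%. Lists not called had an adjusted p of at least 0.0548.

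**Figure D3:**
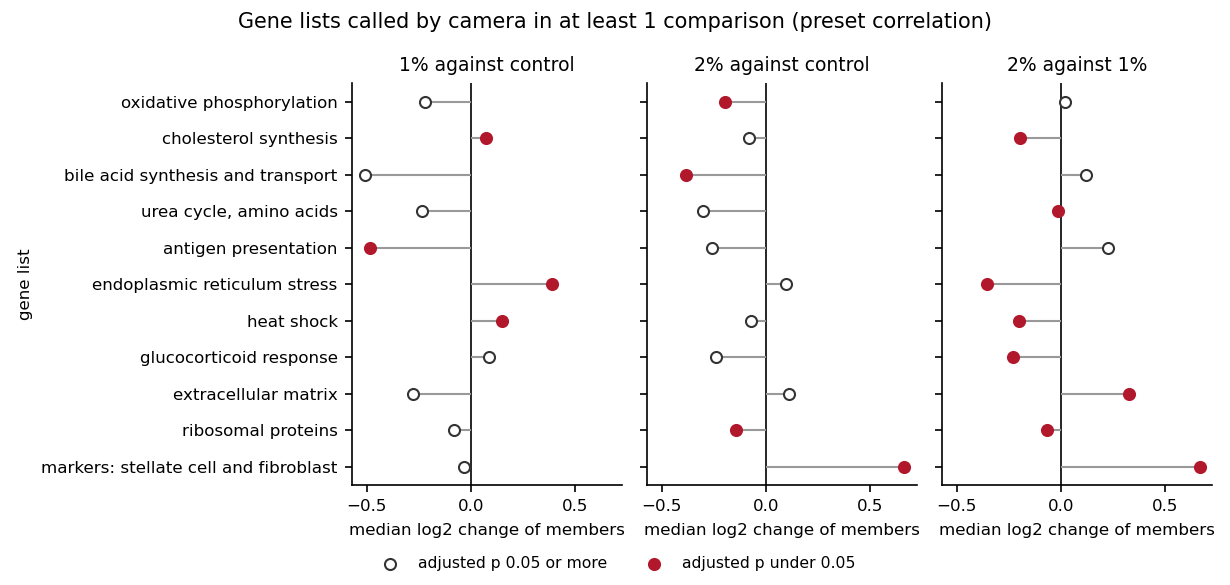
Median log2 change of the members of each gene list called in at least 1 comparison (x axis, log2 units), for 1% against control, 2% against control and 2% against 1% succinate. Filled points had a camera adjusted p under 0.05 at the preset correlation, and with an estimated correlation no list was called. The endoplasmic reticulum stress list lay at 0.389 at 1% and at -0.355 for 2% against 1%.

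A linear trend with dose was fitted to ask which genes were ordered by dose. ANKS6 rose by 0.71 log2 units per percent of succinate (SE 0.074, adjusted p = 0.00929) and ALAS1 fell by 1.11 (SE 0.116, adjusted p = 0.00929), from 155.6 ± 43.8 FPKM in controls through 75.8 ± 12.7 at 1% to 31.6 ± 2.44 at 2%. With 1 gene known only by an identifier, 3 genes passed, 1 higher and 2 lower. Not passing were ARNTL (0.84 per percent), CRY1 (0.70), PALMD (0.69), the acyl-CoA thioesterase ACOT6 (0.61), CIART (-0.77), USP2 (-0.94), the lectin receptor CLEC2D (-0.58) and NR1D2 (-0.71). The count was 0 without control 1, 2% library 1 or 2% library 3, 1 without control 2 (where ANKS6 had an adjusted p of 0.0702) or 2% library 2 (ALAS1, 0.0921), and 5 without 1% library 1, where ARNTL (0.0293) and CIART (0.0452) passed too. It was 0 with the library of conflicting labels at 2% and 1 with the filter at a mean FPKM of 5.

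Both doses were set against the same controls, and their log2 changes had a Pearson r of 0.567 across 11944 genes, which are not independent replicates. Unchanged groups simulated against shared controls gave a mean r of 0.454 (range -0.569 to 0.905 over 100 simulations). The covariance was 0.0652 against a simulated mean of 0.0391, and 18 of the 100 simulations reached it. Of the genes tested, 71.3% had the same sign at both doses, against 65.6% in the simulations. The overlap of calls was 1 lower gene, USP2, and 0 higher, where independent lists would share 0.00067 lower genes. The 3 controls were not split between the doses, so part of any excess may come from the shared controls.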

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

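Leaving out libraries and estimating the correlation were settings chosen beforehand, but these tests of the endoplasmic reticulum stress list were chosen as such only after the result was seen, while the fibrinogen test was set before its result. The splits of the libraries for list counts were also chosen after the result. Outlying libraries were not searched for in groups of 3.

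In the direct comparison of the doses 8 gene lists were called at the preset correlation, and 0 with an estimated correlation (adjusted p = 0.889 for each). The median log2 change at 2% relative to 1% was -0.355 for endoplasmic reticulum stress, -0.201 for heat shock, -0.197 for cholesterol synthesis, -0.068 for ribosomal proteins, -0.228 for glucocorticoid response, -0.016 for urea cycle and amino acid catabolism, 0.325 for extracellular matrix and 0.667 for stellate cell and fibroblast markers. Other splits of the libraries gave many list calls too. Of the 10 splits of the 6 libraries of 1% and 2%, the real one included, 6 called as many lists as the real split, which gave 8, and the highest of the others called 12. For 1% against control 8 of the 10 splits called as many as the real 4, with up to 17 in another, and for 2% against control 10 of the 10 splits did, with up to 14. The 10 splits are too few for a share under 0.05. Whether list calls in splits that mix the groups come from members that vary together or from another structure of the libraries was not tested.

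The endoplasmic reticulum stress list was called higher at 1% than in controls at the preset correlation (median log2 change 0.389, 20 of 23 members), but not with an estimated correlation (adjusted p = 0.861), and 0 members passed adjusted over the list alone. Without each 1% library in turn the call at the preset correlation held (highest adjusted p = 0.00024, camera), but the median was 0.161 without 1% library 3. That p assumes members that hardly vary together, so it cannot exclude a single library. The mean log2 level of the list was 6.52 in 1% library 3, above the highest control (6.109, control 1). In 1% libraries 1 and 2 it was 5.607 and 6.052, within the range of the controls. The members varied together, with an estimated correlation of 0.614, so libraries that differ in this program as a block may have produced the call. With the fibrinogen level of each library as a covariate the median fell from 0.389 to 0.07 (adjusted p = 0.294), as a secretory or acute phase state in some libraries would give. The log2 fibrinogen level was 13.941 and 13.616 in 1% libraries 2 and 3, against at most 13.09 in controls. The covariate therefore takes up part of any group difference, whatever its cause. Control 1, with the highest list level among controls, had a lower fibrinogen level (12.518) than control 2 (13.09). A diet effect acting on both fibrinogen and this list stays open and was not tested.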

How the results depend on the processing

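The fit with voom on recovered reads, median-ratio scaling of the lists, and every alternative for either dose against control were chosen after seeing the data. The counts of genes and of lists were unstable, and the cause was not tested. For 1% against control the count of 2 became 0 with a pseudocount of 0.1, no filter, a mean FPKM of at least 5, quantile or median-ratio scaling, voom, or the 2 groups alone. For 2% against control the count of 6 became 3 without a filter, 1 with a mean FPKM of at least 5, 3 with voom and 0 with the 2 groups alone. The trend count of 3 became 1 with a mean FPKM of at least 5. For either dose against control the count of 9 became 3 with a pseudocount of 0.1, 1 without a filter, 4 with a mean FPKM of at least 5, 5 with quantile and 3 with median-ratio scaling. With the library of conflicting labels at 2% these 4 counts were 0, 1, 0 and 1, in the order 1%, 2%, trend and either dose. At an unadjusted p under 0.05 with at least a 1.5-fold change they were 966, 331, 51 and 473, and 431 for 2% against 1%. Leaving out each library in turn gave 0 to 4 genes for 1%, 0 to 7 for 2%, 0 to 1 for 2% against 1%, 0 to 5 for the trend and 0 to 11 for either dose.

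Lists called by camera numbered 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry for 1%, 2% and 2% against 1%, while fry's test for change in either direction called 3, 2 and 2. For 1% the count of 4 became 8 with quantile and 2 with median-ratio scaling, and for 2% it became 1 with quantile scaling. Leaving out each library gave 3 to 11, 1 to 11 and 4 to 10 lists. The log2 ratio of hepatocyte to muscle markers was 11.78 as a mean over members, again with 1 added to each level, which lowers the ratio. The correlation between doses was 0.454 in simulated unchanged groups.

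With a replicate block the count was 0 for 1%, 1 for 2%, 0 for the trend and 1 for either dose. The numbers do not pair the libraries: correlations of same-numbered libraries ran from -0.295 to 0.278, 2 of 9 pairs were over 0.1, and 2 of 9 libraries were closest to their own number.

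For the 9 results of named genes that passed, 78 of 164 alternative values kept the call and 86 lost it. Alternatives in which a gene was not tested, as when it fell below the filter, are left out of the counts for named genes. For the 16 called lists, 164 of 256 kept it, 91 lost it and 1 reversed relative to all other genes. The median changed sign in 11 of the 256, 8 of them when a library was left out. Over all 117 results for named genes, most of which had no call to lose, 2197 of 2293 alternative values kept direction and side of the threshold, 3 gained a call and 7 reversed, 3 of them when a library was left out. SDHB reversed to 0.024 at 1% with median-ratio scaling and to -0.048 at 2% with the relabelled library. That relabelling also reversed, for 2% against 1%, ATF6 to 0.08, SLC25A10 to -0.08 and the endoplasmic reticulum stress list to 0.117. Without 1 library, SDHB at 2% ranged from -0.042 to 0.122. Depth limits genes near 1 FPKM, and simulated 2-fold changes were found for 29.9% of genes at 1% against control.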

Other observations

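The scaling and leave-one-out tests of the clock genes, the scaling and left-out-library tests of the excess of lower values, and the comparison of either dose with control were chosen only after the result was seen. The test of the remaining clock genes, the gene length test and the splits of the libraries for gene counts were set before their results.

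In the growth and insulin signalling list 4 of 21 members, all higher at 2% than at 1%, passed adjusted over the list alone, and 0 passed over all genes. Fry's test for change in either direction gave an adjusted p of 0.00562, and 0.0101 for myogenic regulation, which shares IGF1, while camera did not call the list (adjusted p = 0.0745, and 0.889 with an estimated correlation) except after quantile scaling (0.0285). The 4 members were IGF1 (log2 change 2.04), SOCS2, the feedback inhibitor of growth hormone signalling (2.33, from 8.14 ± 7.32 to 38.7 ± 15.3 FPKM), IGFBP3, a carrier of the growth factor (1.06, from 92.9 ± 29.3 to 198.4 ± 77), and the hepatokine FGF21 (1.94, from 11.7 ± 8.08 to 41.2 ± 2.09). In controls SOCS2 was at 20.6 ± 5.14, IGFBP3 at 189.9 ± 16.7 and FGF21 at 37.1 ± 13.9 FPKM, and the mean at 1% was the lowest for each. Against control at 1%, FGF21 passed adjusted over the list alone, and SOCS2 and IGFBP3 did not. IGF1 was higher at 2% than in controls (1.54, limma, adjusted p = 0.00651 over the list alone, and 0.264 over all genes). SOCS2, IGFBP3 and FGF21 were named after their values were seen.

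Set together, the 6 succinate libraries differed from the 3 controls in 9 genes, 2 higher and 7 lower (limma). Beside USP2, ANKS6, ARNTL, ALAS1, CIART, SMIM10 and 1 gene with only an identifier, these were DBP (log2 change -1.72, adjusted p = 0.0429) and TSKU, a protein secreted by the liver, which fell from 45.2 ± 12.5 FPKM in controls to 6.62 ± 3.26 at 1% and 6.4 ± 4.06 at 2% (-2.70, adjusted p = 0.0398). The count was 0 without any 1 of the 3 controls, 4 without 1% library 2, 1 without 1% library 3, and 2, 3 and 2 without 2% libraries 1, 2 and 3. USP2 and CIART exceeded 1 FPKM only in controls and fell below the filter when a control was left out. Of 100 splits of the 9 libraries 1, the real one, gave as many genes and the highest of the others gave 3. That share is under 0.05, but this comparison was picked after both doses had been seen to share genes. For the trend 4 of 100 splits gave as many as the real 3 genes, and the highest other gave 5. For single doses the 10 splits of 6 libraries are too few for a share under 0.05: the real counts were 2 at 1%, 6 at 2% and 0 for 2% against 1%, reached in 1, 1 and 10 splits, and the highest others were 0, 1 and 1.

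In the circadian clock list 4 genes were higher and 9 lower in the succinate libraries when adjusted over the list alone, and the groups did not overlap for 10 of 18 genes, where chance gives 2.38%. Over all tested genes the groups did not overlap for 521 of 11944, where chance gives 284. A candidate explanation is that the clock stood at another phase in the livers of the succinate groups. It was tested on members outside those first seen: NPAS2, CLOCK and NFIL3, taken as the arm of ARNTL, against PER1, PER2, NR1D1, TEF and HLF. BHLHE41 was also planned for the second arm but was not among the tested genes. The difference between arms was 1.12 log2 units larger in succinate libraries (exact permutation p = 0.0119, the smallest possible over 84 splits, 6 against 3 libraries). NPAS2, NFIL3, PER1 and PER2 on their own overlapped between the groups, and NFIL3 went against its arm (-0.18). Both arms belong to the list in which the change was first seen, so this p is not independent evidence. Nor can it tell another phase from a change in the level of these genes. The median absolute change of ARNTL, CRY1, CIART, DBP, NR1D2 and PER3 was 1.45 after rescaling and at least 1.36 without each of the 9 libraries. CIART was not tested when a control was left out. These 6 genes had the smallest p of the list in these same data. Rescaling moves all genes of a library by 1 factor, so it could hardly have removed changes of this size in both directions. The median change of these 6 genes held without each library, an outcome favoured by choosing them for their small p. These values do not speak for the other members. Per the labels the sheep were fed on 1 schedule, but no time of slaughter is given, so whether diet or the hour at which each group was sampled shifted these genes stays open and was not tested.

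At 1% succinate, 85.8% of the genes with an unadjusted p under 0.05 were lower than control. The share did not rest on library 3 at 1% alone, which carries conflicting dose labels, as it was 88.7% without it. The number of lower genes did depend on that library, falling from 1526 to 754 without it, against 2043 and 1123 without 1% libraries 1 and 2 and 298 expected by chance. This leaves its part in that number open. Without control 1 the excess was smaller, with 712 genes higher and 1143 lower. The change was hardly related to relative gene length, with a Spearman rho of -0.016 across 11942 genes. After median-ratio rescaling the share was 46.9%, but centring the typical gene near 0 fixes that outcome, so it does not decide whether scaling of FPKM or a true fall of many transcripts lies behind the excess, and both stay open. The 10 genes with the highest FPKM held 17.6, 21.36 and 20.94% of all FPKM in controls 1, 2 and 3. They held 21.22, 26.75 and 26.7% in 1% libraries 1, 2 and 3. In 2% libraries 1, 2 and 3, with 492 genes lower in that comparison, they held 23.32, 24.78 and 25.18%. A larger share for a few genes lowers the FPKM of the rest. How much of the excess this accounts for was not tested.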
